A study of Arabidopsis thaliana with 12 samples.

How the data were processed

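Total RNA from wild-type Arabidopsis thaliana of the Columbia 0 ecotype, the common laboratory strain of this plant, was measured on expression arrays, with 6 samples labelled 4 weeks and 6 labelled 2 weeks. The labels do not name the organ, the growth conditions or the number of plants behind a sample, and they do not say whether the 6 samples of an age are separate plants, separate extracts or repeated measurements of 1 extract. The deposited table holds 1 intensity per probe and sample for 3439 probes, and none of its columns was left out. How the authors read, background-corrected and scaled these intensities is not given in the sources used here.

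Some of it can be read from the deposited intensities themselves. They are linear, run from 0 to 100 in each sample and are never negative, and between 3 and 7 probes of a sample stand at 100 to within 0.01. In all, 10 probes reached 100 in at least 1 sample, and none of the genes named in the text did. Between 421 and 694 probes of a sample stand at exactly 0. Whether a value of 0 is a failed spot or a signal at or under background is not given in the sources used here, and 100 is taken as the top of the scale. The number of arrays limits the precision.

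Array medians of positive values differed by 1.90 on the log2 scale. A rule set before the data were examined called for quantile normalization above a difference of 0.2, so the arrays were quantile normalized. Values under the 1st percentile of the positive normalized intensities, 0.0152, were set to it, and log2 was taken. A probe was kept if it lay above this floor on at least 6 of the 12 arrays, which left 2961 probes or genes to test and 477 out. Of the probes, 124 were at 0 in all 12 samples. The 1 pair of probes for the same gene was averaged. Changes were tested with limma's lmFit and eBayes (limma 3.58.1 in R 4.3.3), two-sided, 4 weeks minus 2 weeks, with Benjamini-Hochberg adjustment and a threshold of 0.05. Where a gene lay at the floor in all samples of an age, its fold is given as a lower bound against the floor. For the share of signal in the brightest probes and similar measures per array, an exact two-sided permutation test over the samples was used on the deposited intensities.

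Probes were named through the array's annotation table. Of the probes, 692 had 1 gene there, 870 had several and were not named, and 1877 were not listed and remain unnamed here. Of the 692, 690 were matched to the RefSeq gene table of assembly TAIR10.1, which was used for names only. The array's own genome build is not given in the sources used here, so no coordinates are printed. After filtering, 593 named genes were tested.

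Before the data were examined, 22 gene lists holding 406 loci were fixed from textbook plant biology, covering photosynthesis, chlorophyll and plastid functions, metabolism, defence, cell division, other organs and reference genes. The array's single-gene probes reached 18 of these loci, of which 16 were tested, and 14 lists had no tested member. The photosystem II list, with 4 tested members, and the plastid ribosomal protein list, with 5, had at least 3 and were tested with camera at its preset correlation of 0.01, with an estimated correlation and with fry as alternatives. A combined list of photosystem I, photosystem II, electron carriers and Calvin cycle was added after the data were seen.

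The genes named in the text follow a rule fixed before the data were examined. They are the 10 largest rises and 10 largest falls among named genes with an adjusted p below 0.05, no overlap between the ages, and a mean level in the brighter age above the first quartile of the tested probes, and from each list with at least 3 tested members the 3 largest changes among those that passed. The other tested list members, 5 further rises and 5 further falls measured above the floor on all 12 arrays, and the genes that open the last part of the closing section were chosen after their values were seen.

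The labels number the samples of each age from 1 to 6. Deviations from the age means were correlated between samples of the same number at 4 and 2 weeks, with Pearson's r across genes, which are not independent replicates. The 6 correlations ran from 0.16 to 0.44, and 12 of 12 samples matched the sample of their own number best in the other age. By the rule used here, a correlation above 0.1 in each pair, the numbers pair the samples, although the labels do not say what a number stands for. Within an age, adjacent numbers (1 and 2, 3 and 4, 5 and 6) also deviated together, with r from 0.41 to 0.50 at 4 weeks and from 0.01 to 0.31 at 2 weeks, against -0.47 to -0.22 for the other pairs of an age. The samples may therefore be fewer than 6 independent units per age, and counts are given also with adjacent numbers averaged, 3 against 3.

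The test was tried on simulated data with the real levels and spreads of the comparison of 4 with 2 weeks, with 200 changed genes. With independent spread over 2961 genes, it recovered 26.9% of changes of 1.5-fold, 62.7% of 2-fold and 89.4% of 4-fold, and 4.03% of its calls were false. With spread shared within adjacent numbers, over 2958 genes, 29.1% of the calls from the 12 samples were false. Averaging adjacent numbers brought this to 6.49% and recovered 1.49%, 31.3% and 75.8% of the changes. In the same simulations, camera gave a p below 0.05 for 0% and 1% of 200 random lists of 6 genes and for 100% of 50 lists shifted by -1 on the log2 scale. Only 200 genes changed in the simulations, whereas 1914 of 2961 were called in the real data. The simulations started from normalized levels, so they lack the difference in array medians between the ages. Spread shared by adjacent numbers was drawn separately in each age. These rates therefore need not hold in the real data. The real photosystem II list, shifted by -1.37 against other genes, did not pass in camera.

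The alternatives set before the data were examined were the deposited values without normalization, median centring, a floor at the 5th percentile, a pseudocount, no filter on dim probes, the dimmest 25% left out, the brightest probe per gene, the replicate number as a fixed or random block, eBayes with trend and robust settings, array weights, each sample left out in turn and a minimum change of 2-fold. Averaging adjacent numbers, a random block on them, and leaving out 2-week samples 1 and 2, 4-week samples 3 and 4 or samples 3 and 4 of both ages were added after the data were seen.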

Results

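The series compares gene expression in wild-type Columbia 0 Arabidopsis plants at 2 ages, 2 weeks and 4 weeks, with 6 samples of each. Intensities of 3439 probes were measured in total RNA. The array median of the deposited intensities was 0.412 ± 0.024 (SD, n = 6) at 4 weeks and 0.108 ± 0.00931 at 2 weeks, and 13.2% ± 0.583 and 17.7% ± 1.67 of the probes stood at 0. Spearman's rho across probes ran from 0.872 to 0.975 between samples of the same age and from 0.581 to 0.699 between ages.

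Of 6 tested genes of the photosynthetic apparatus, 4 fell at 4 weeks against 2 weeks and the other 2 did not pass. PSAN, a subunit of photosystem I, had a normalized intensity of 2.54 ± 0.39 (SD, n = 6) at 4 weeks and 11.4 ± 2.82 at 2 weeks, a 4.42-fold fall. PRK, the phosphoribulokinase of the Calvin cycle, fell from 4.08 ± 0.367 to 0.701 ± 0.0632, which is 5.82-fold. The light-harvesting antenna gene LHB1B2 fell 2.69-fold, from 39.0 ± 6.5 to 14.6 ± 2.58. PSBY, a small photosystem II protein, fell 8.77-fold, from 4.88 ± 1.93 to 0.703 ± 0.444.

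The 6 genes are the tested members of the photosynthesis lists as a whole, and 0 of them rose. Adjusted over the list alone, 5 fell and 0 rose. The log2 fold changes were -2.15 (SE 0.17) for PSAN, -2.54 (SE 0.10) for PRK, -1.43 (SE 0.16) for LHB1B2 and -3.13 (SE 0.62) for PSBY. Their adjusted p-values in the limma fit were 2.22e-07 for PSAN, 7.23e-10 for PRK, 5.60e-06 for LHB1B2 and 7.29e-04 for PSBY. That fit takes the 6 samples of an age as independent. With adjacent numbers averaged, limma gave adjusted p-values of 2.82e-04 for PSAN, 1.29e-04 for PRK, 0.00286 for LHB1B2 and 0.0234 for PSBY. The SE of PSBY was then 0.85. The 4 falls were also called in the deposited values without normalization, with median centring and with adjacent replicate numbers averaged. Median centring gave larger changes, -4.02 for PSAN, -3.80 for PRK, -3.56 for LHB1B2 and -4.46 for PSBY. For PSBY, samples 3 and 4 lay low in both ages, with a mean log2 level of -2.86 against -0.03 in the other samples at 4 weeks and of 1.27 against 2.61 at 2 weeks. Without samples 3 and 4 of both ages its log2 fold change was -2.65 (SE 0.13).

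The members that did not pass were PSB27 and PSBW. PSB27, a photosystem II assembly protein, had a log2 fold change of -1.17 (SE 0.50, adjusted p = 0.058 in limma), and with replicate number as a block it passed, at an adjusted p of 0.00151. PSB27 was also called a fall under median centring, at -2.32, and its adjusted p was 0.0487 with the floor at the 5th percentile, 0.0497 with the dimmest 25% left out and 0.0470 with trend and robust eBayes in limma. PSBW, another photosystem II subunit, went the other way, at 0.56 (SE 0.29, adjusted p = 0.109 in limma). With the block PSBW passed as a rise, at an adjusted p of 0.00709, whereas under median centring it was called a fall, at -1.82. With adjacent numbers averaged neither passed, at adjusted p-values of 0.208 for PSB27 and 0.290 for PSBW. That fit does not pair the ages. In normalized intensity, PSB27 was lower and PSBW higher at 4 weeks for each replicate number. In the deposited values PSBW was lower at 4 weeks for numbers 3, 4, 5 and 6, and higher for numbers 1 and 2. Adjacent numbers deviated together, so neither the numbers nor the block fit need rest on independent pairs.

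The median log2 fold change over the 6 genes was -1.79. Against all other genes, the shift of the combined list gave a camera p of 0.0176, two-sided, and p = 0.0377 with an estimated correlation. The mean of the list less that of the other genes was -1.72, and -3.47 under median centring. The combined list was put together after the data were seen. The photosystem II list on its own, with 4 tested members, had 2 that fell, 0 that rose and 2 that did not pass, with the same counts when adjusted over the list alone. Its median was -1.30, and its shift against other genes did not pass in camera (adjusted p = 0.441, and adjusted p = 0.547 with an estimated correlation). It passed on the deposited scale (adjusted p = 0.00144) and under median centring (adjusted p = 0.0296).

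**Figure D1:**
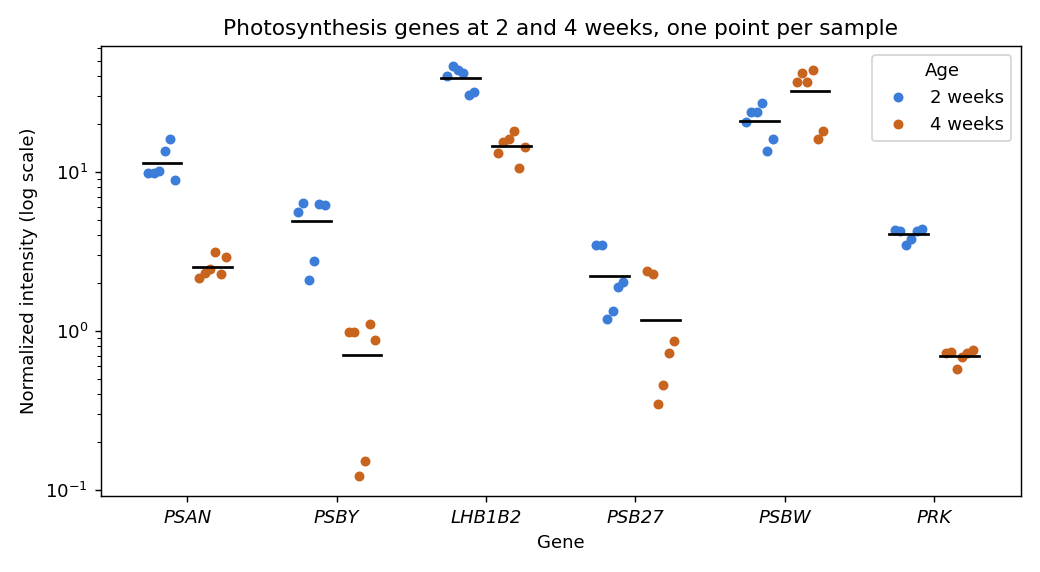
Normalized intensity, on a log axis, of the 6 tested photosynthesis genes. Each point is a sample, drawn from left to right in the order of the replicate numbers 1 to 6, and bars are means of 6 samples. PSAN, PSBY, LHB1B2 and PRK lie lower in each 4-week sample than in each 2-week sample, while PSB27 and PSBW overlap between the ages.

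The chlorophyll synthesis list had 2 tested members, and the lists for fatty acids, assimilation and antioxidant enzymes 1 each. AT1G74470, the geranylgeranyl reductase that makes the chlorophyll side chain, fell by 1.49 on the log2 scale (SE 0.17), from a normalized intensity of 4.27 ± 0.773 to 1.53 ± 0.343 (SD, n = 6). CHLM, a methyltransferase of the same pathway, fell by 0.68 (SE 0.12), but was higher at 4 weeks by 0.77 in the deposited values. FATB, the acyl-ACP thioesterase that releases saturated fatty acids, fell by 3.95 (SE 0.64), with 4 of its 4-week samples at the floor. With the floor at the 5th percentile FATB fell by 2.65. APS4, an ATP sulfurylase, had a change of -0.68 (SE 0.23, adjusted p = 0.0234 in limma). Its call was lost with adjacent numbers averaged (adjusted p = 0.0707) and under median centring, at -0.34 (limma adjusted p = 0.342). In the deposited values APS4 was called a rise, at 1.37 (limma adjusted p = 0.00076). AT3G52960, a plastid peroxiredoxin, rose by 2.70 (SE 0.70), or 1.76 with the floor at the 5th percentile, with 3 of its 2-week samples at the floor. With adjacent numbers as a random effect its adjusted p was 0.0824.

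Plastid ribosomal protein genes went both ways. Of 5 tested members, 1 rose, 2 fell and 2 did not pass, with the same counts when adjusted over the list alone. AT3G54210, for protein L17, fell by 1.48 (SE 0.49), and lay lower at 4 weeks for each of the 6 replicate numbers. Its samples 3 and 4 were low in both ages, at a mean log2 level of -2.45 against -0.22 in the other samples at 4 weeks and of -0.19 against 0.86 at 2 weeks. AT4G01310, for L5, fell by 1.11 (SE 0.14). AT5G65220, for L29, rose by 0.53 (SE 0.20) but stood at -0.29 under median centring. The changes of AT1G29070, for L34, and AT3G13120, for S10, were 0.24 (SE 0.83) and 0.09 (SE 0.55). The list's median was 0.09 and its mean -0.34, so these differ in sign, and camera gave an adjusted p of 0.588 (adjusted p = 0.592 with an estimated correlation). With adjacent numbers averaged, AT4G01310 was the 1 member called, at an adjusted p of 0.00570. In the deposited values 2 members were called higher, AT5G65220 and AT3G13120, and 0 lower, with AT3G54210 at -0.61 (adjusted p = 0.275 in limma) and AT4G01310 at 0.19.

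Over the 16 tested members of the lists, 10 fell, 2 rose and 4 did not pass; adjusted over the list alone, taking the 16 as one list, 11 fell and 2 rose. In the deposited values 6 of the 16 were called lower, 5 higher and 5 did not pass. With adjacent numbers averaged, 8 fell, 1 rose and 7 did not pass.

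DRT101, a gene named for tolerance of DNA damage, rose at 4 weeks with a log2 fold change of 5.72 (SE 0.32). It was at the floor in 5 of the 6 samples at 2 weeks, so 1 of them measured it and the size of the fold rests on the floor, with 4.09 at the 5th percentile floor. Its normalized intensity at 4 weeks was 1.01 ± 0.339 (SD, n = 6). AT1G07040 was at the floor in all 6 samples at 2 weeks and at 0.485 ± 0.173 at 4 weeks, at least 30.4-fold higher against the floor used here and at least 8.24-fold against a floor at the 5th percentile. AT2G32470 rose by 4.94 (SE 0.30), with 3 of its 2-week samples at the floor. LpxA, named for an acyltransferase of lipid A-type synthesis, rose by 3.71 (SE 0.44), with 2 such samples.

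The other large rises were those of AT2G46190 at 4.49, AT2G23890 at 4.35, AT5G52530 at 3.91, AT3G52550 at 3.87, AT3G13150, a pentatricopeptide repeat protein gene, at 3.84, and AT1G62760, of the invertase and pectin methylesterase inhibitor family, at 3.78. Between 1 and 5 of the 6 samples at 2 weeks were at the floor for each of these. Without 2-week sample 5 the change of AT3G52550 was 4.55. For rises with no sample at the floor, AT1G06510 reached 3.53 (SE 0.26), AT2G46850 3.15 (SE 0.17), AT4G20300 3.12 (SE 0.12), AT1G10310 3.08 (SE 0.17) and AT1G16080 3.02 (SE 0.13). The last of these was the brightest of the 5, at 12.5 ± 1.1 (SD, n = 6) at 4 weeks and 1.55 ± 0.246 at 2 weeks.

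Among the falls, AT1G51080 went from 0.959 ± 0.0946 (SD, n = 6) at 2 weeks to 0.0631 ± 0.0401 at 4 weeks, a log2 fold change of -4.15 (SE 0.35). AT5G63390 changed by -3.64 (SE 0.17), or -1.87 with the floor at the 5th percentile, with 5 of the 6 samples at 4 weeks at the floor and 1 measuring it. AT5G19940, of the plastid-lipid-associated fibrillin family, changed by -3.52 (SE 0.36), PRA1.B3 by -3.43 (SE 0.66) and AT1G64430 by -3.32 (SE 0.13). AT5G19940 was at the floor in 2 samples at 4 weeks and PRA1.B3 in 1, 4-week sample 4, without which its change was -2.83.

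AT2G38070 changed by -3.31 (SE 0.11), AT2G39670 by -3.10 (SE 0.32) with 2 samples at the floor, and AT5G19210, a DEAD-box RNA helicase gene, by -3.06 (SE 0.11). Further falls with no sample at the floor were those of AT3G47650, the BSD2 chaperone of Rubisco assembly, at -3.06 (SE 0.12), AT2G04700 at -2.83 (SE 0.44), AT1G33250 at -2.62 (SE 0.15), ILA at -2.61 (SE 0.21) and AT1G04420 at -2.55 (SE 0.20). AT3G47650 had a normalized intensity of 4.94 ± 0.638 (SD, n = 6) at 2 weeks and 0.592 ± 0.0755 at 4 weeks. With the floor at the 5th percentile, the fold of 13 of the 20 largest changes, 9 rises and 4 falls, moved by over 1.5 times, and all 20 were still called. The rises then ran from 2.2 to 4.09 and the falls from -3.75 to -1.87. These 20 largest changes and 10 further ones kept their direction and their call in the deposited values, with median centring and with adjacent numbers averaged.

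**Figure D2:**
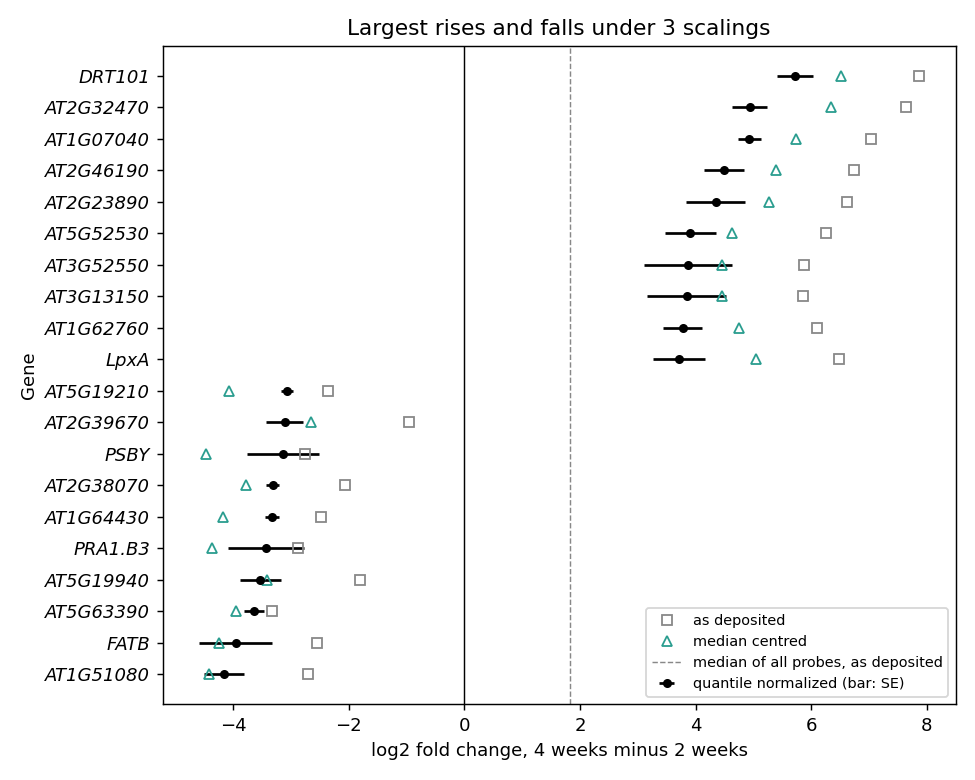
The log2 fold change, 4 weeks minus 2 weeks, of the 10 named genes with the largest rise and the 10 with the largest fall. Filled circles are the quantile normalized values with their SE, squares the deposited values, triangles median centring, and the dashed line is the median of all probes in the deposited values, 1.82. The 20 genes keep their direction under these 3 scalings.

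Across the array, limma called 1914 of 2961 tested probes and genes at an adjusted p below 0.05, 994 higher and 920 lower at 4 weeks, and 666 and 631 of them changed at least 2-fold. Among the 593 named genes tested, 236 were higher and 160 lower. With adjacent numbers averaged, 751 were higher and 756 lower, of which 742 and 746 were also called in the same direction from the 12 samples. In the deposited values without normalization the split was 2245 higher and 327 lower, with a median log2 fold change over all probes of 1.82, and 342 probes called lower after normalization were called higher there. Under median centring the split was 978 higher and 922 lower. Of the 1914 calls, 1611 were kept there in the same direction and 27 were called in the opposite direction. Quantile normalization and median centring both bring the arrays to a common level, so near-even splits follow at least in part from the scaling. Under all 3 scalings, 823 were called higher and 324 lower, out of 2958 tested in each. The deposited values, with 327 called lower, cap the second count. The larger number of rises therefore follows at least in part from the values left without normalization.

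The distribution of signal over the probes differed between the ages. The brightest 1% of the probes, 34 in each sample, held 34.9% ± 1.4 of the summed deposited intensity at 4 weeks and 56.0% ± 0.836 at 2 weeks (SD, n = 6, exact two-sided permutation p = 0.00216, the smallest that 6 against 6 can give). With adjacent numbers averaged the exact p was 0.1, the smallest that 3 against 3 can give. Sorted by mean level over the 12 samples, the brightest 1% of tested probes had a median log2 fold change of -1.43 in the deposited values, the next group, from 1% to 5%, -0.92, and the dimmest 25% 2.77. After quantile normalization these medians were -0.84, -1.06 and 0.34.

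**Figure D3:**
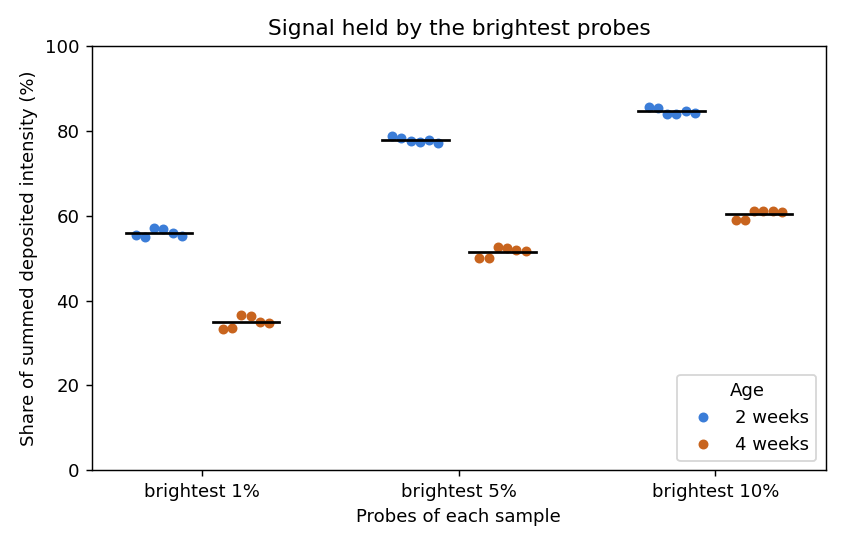
Share of the summed deposited intensity held by the brightest 1%, 5% and 10% of the probes of each sample, in percent. Points are samples in the order of their replicate numbers and bars are means of 6 samples. The 4-week samples lie between 33.3% and 36.7% for the brightest 1%, and the 2-week samples between 55.1% and 57.2%.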

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

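The tests of a uniform background, of material shared within 1 age, of shared hybridisations or extracts, of neighbouring probe numbers and of one scaling factor per array were chosen after the results were seen, as were the combined photosynthesis list and the averaging of adjacent numbers.

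For 9 of 94 groups of 6 values, 1 sample stood apart from the other 5 by more of the range than Dixon's test allows, and chance gives about 1 in 20. In 4 of the 9 the other 5 values had been set to the floor, which fixes the ratio, so the 9 cannot be held against that rate. In normalized log2 intensity, AT3G52550 was highest in 4-week sample 5, at 0.077 against -0.94 in the next sample, and LpxA in 4-week sample 2, at -0.73 against -0.92. PRK was lowest in 4-week sample 3, at -0.78 against -0.54. AT5G63390 was above the floor in 4-week sample 5, at -5.36, and the other 5 stood at the floor, -6.04. At 2 weeks, DRT101 was above the floor in sample 4, at -4.55, AT2G46190 in sample 6, at -4.26, and AT1G62760 in sample 6, at -4.16. AT5G52530 and AT3G13120 were at the floor, -6.04, in 2-week sample 5 alone, with the next samples at -3.95 and -3.41.

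Of 100 splits of the 12 samples into 6 and 6, drawn from 462, 1 called as many genes as the ages did, and that was the split by age itself. It called 1914, and the highest of the others 3. Among the other splits drawn, 11 also part each replicate number between the groups, and the highest count there was 0. Any other split leaves the difference between the ages in its spread, so low counts there follow from that difference. With adjacent numbers as 1 unit, 3 against 3 can give no exact permutation p below 0.1, so chance is not excluded. The splits do not settle how many independent plants stand behind the samples.

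Of the 6 photosynthesis genes tested, 4 fell. The median change of the 6 lay at percentile 2.55 of 10000 random lists matched on level. This rank is one-sided and the list was put together after the data were seen, so it argues only weakly against a fall common to all probes of that brightness. Less the median of all probes, the median change of the 6 was -1.88 under the scaling that moved it least, which argues against one scaling factor per array as the cause. The deposited and median-centred values differ by such factors and are not separate tests, and a difference between arrays that depends on level is not addressed by this value. What remains open is a lower share of these transcripts in older plants, a hypothesis that rests on 6 genes, and a different organ or growth condition between the ages, which the labels do not give.

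The brightest probes held a smaller share of the signal at 4 weeks. If a constant background had been left in the 4-week arrays, no value there should lie far below it, but 59.5% of them lay below the constant that would be needed, 0.522. This outcome was settled by the deposited values, with 13.2% at 0 and an array median of 0.412 at 4 weeks. It cannot speak to a background present before the values were brought to that form. A power law that turns the 2-week share of the brightest 1% into the 4-week one predicts 67.9% in the brightest 10%, where the 4-week arrays had 58.9% to 61.2%. Other differences in labelling, exposure or scaling of the arrays stay open, and so does a true difference in the makeup of the RNA, which was not tested.

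Samples with adjacent replicate numbers deviated together. The mean deviations of the same pair of numbers at 4 and 2 weeks correlated at 0.213 or more across genes, which argues against plant material shared within 1 age as the only cause. The correlation does not speak against such material as a part of the pattern. The adjacent pairing ranked 1 of 15 pairings for closeness in both ages, but the pattern itself fixes this rank, so one hybridisation behind each adjacent pair stays open. In 82 cases, on 75 probes, a pair lay more than 4-fold beyond the other 4 samples of its age. In many of them the pair or the other 4 samples stood at the floor. Of the 82, 28 lay within 5 probe numbers of another of the same pair, where 10000 random draws gave a median of 2 and at most 14. The draws take neighbouring probes as unrelated. Whether neighbouring numbers are neighbouring positions is not given in the sources used here. A local fault of the array may be part of the pattern. The ages shared 5 of the 75 probes over the same pair numbers, with 0.242 expected from independent lists, and all 5 were probes of samples 3 and 4. Over different pair numbers they shared 2, with 0.401 expected.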

How the results depend on the processing

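Averaging adjacent numbers, a random effect for them, leaving out samples together, the combined photosynthesis list and the share of signal with its alternatives were added after the data were seen. Of the 44 genes followed, 34 kept direction and call under each alternative run for them, and 1140 of 1195 values did so over all genes. Most of the 44 were the largest rises and falls or the further ones, picked from these data for large changes that passed. That choice favours keeping a call, and none of them lost direction or call. All the genes that changed were list members outside that choice. Among such list members, only PSAN, LHB1B2, PRK and AT1G74470 kept both throughout. Signals near the floor limit the size of the folds given for genes with few samples above it.

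The deposited values moved the counts to 2245 higher and 327 lower, because their median change is 1.82. They also turned PSBW to -0.12, CHLM to 0.77, AT4G01310 to 0.19 and APS4 to 1.37. Median centring turned PSBW to -1.82 and AT5G65220 to -0.29. The mean shift of the photosystem II list against other genes passed at -3.12 in the deposited values and -3.18 under median centring. In fry, which tests a list by itself, photosystem II passed with a mean change of -1.29 and plastid ribosomal proteins with -0.34. Their shifts against other genes, which fry does not test, are -1.37 and -0.42. The causes were not tested.

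AT1G29070 and AT3G13120, which did not pass, changed sign, although AT3G13120 passed as a rise of 2.38 in the deposited values. For AT1G29070 the value was -0.18 with array weights, -0.20 without 4-week samples 3 and 4, -0.29 without samples 3 and 4 of both ages, and negative, between -0.15 and -0.05, in 4 of the fits that left out 1 sample, which ranged up to 0.65. For AT3G13120 it was -0.22 with the floor at the 5th percentile, -0.016 with a pseudocount, and from -0.46 to 0.36 with 1 sample left out, negative without 2-week replicate 5 and without 4-week replicate 6.

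Leaving out 1 sample at a time gave 901 to 995 genes higher and 877 to 912 lower. AT5G65220 lost its call in 6 of these fits and APS4 in 3, while PSB27 gained one in 3 and PSBW in 2. The list shifts ranged from -1.48 to -1.18 for photosystem II, from -0.53 to -0.30 for plastid ribosomal proteins and from -1.79 to -1.57 for the combined photosynthesis list. The difference in the share of the brightest 1% ranged from -21.4 to -20.7 percentage points. Averaging adjacent numbers left it at -21.0, but 3 against 3 cannot pass the threshold.

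With the replicate block, 1041 genes were higher and 987 lower, and 1871 of the 1914 calls were kept. Among the genes followed, PSB27 and PSBW gained a call under the paired fit, and no other call of these genes or lists changed.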

Other observations

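The genes in this paragraph were chosen after their values were seen, from named genes outside the lists. LAS, the GRAS-family regulator Lateral Suppressor that acts in axillary meristem formation, had a log2 fold change of 3.0 (SE 0.14) and a normalized intensity of 1.98 ± 0.367 (SD, n = 6) at 4 weeks and 0.247 ± 0.0351 at 2 weeks. AILP1 rose by 2.11 (SE 0.11), from 0.599 ± 0.0655 to 2.57 ± 0.178. LAS and AILP1 were called in the same direction in the deposited values and under median centring.

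Among falls, RAP74 changed by -1.70 (SE 0.14) and PRA1.B6 by -1.41 (SE 0.11), and both were also called lower in the deposited values, at -1.60 for RAP74 and -1.21 for PRA1.B6. CYN, the cyanase gene, changed by -2.15 (SE 0.23) and by -0.75 in the deposited values, a call in both. THIC, an enzyme of thiamine synthesis, changed by -1.62 (SE 0.16), but its -0.23 in the deposited values did not pass. LPA19, a photosystem II assembly gene outside the lists, changed by -1.46 (SE 0.23) and turned to 0.74 in the deposited values.

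NdhS, a subunit of the plastid NADH dehydrogenase-like complex, changed by 0.60 (SE 0.15), and CRR21, an editing factor of the same complex, by 0.73 (SE 0.16). NdhS lost its call with adjacent numbers averaged (limma adjusted p = 0.0703) and turned to -0.92 under median centring. CRR21 kept its call in both.

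Some probes were at 0 throughout 1 age. At 4 weeks 151 probes were at 0 in all 6 samples but not in all 12, and at 2 weeks 112 were. By count of probes on which an adjacent pair lay more than 4-fold beyond the rest of its age, 4-week samples 3 and 4 stood apart on 23, with the pair lower on each, 2-week samples 1 and 2 on 19, again with the pair lower on each, and 2-week samples 3 and 4 on 20, with the pair lower on 17 and higher on 3. The other 3 pairs stood apart on 6 or 7 probes. On many of these probes the pair, or the rest of its age, stood at the floor, -6.04 in log2. The size of the gap there rests on the floor. AT1G13370, among the 19, was not at the floor. Its mean log2 level was -0.28 in 2-week samples 1 and 2 and 2.23 in the other samples of that age.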
